A study of Mus musculus with 6 samples.

How the data were processed

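Total RNA of 6 samples of SmoWT-MB cells (3 groups of 2) had been extracted with Trizol, labelled as biotinylated cRNA and hybridised to Illumina mouse BeadArrays, per the labels' protocols. The deposited non-normalized table gives an average signal intensity and a detection p-value per probe and array. Its intensities were summarised with GenomeStudio 1.9.0, per the submitters' processing notes, and are neither background-subtracted nor scaled between arrays, as the values show (lowest 28.9, never negative). The deposited detection p-values run in steps of 1 in 936, the number of negative control beads that the values imply. The authors' processed values, a deposited table of intensities on a linear scale, hold 30847 gene entries, of which 30825 were matched by name. In these values 28.3% lie below 0, the median of each array is 8.15 and 88.5% of the sorted values are equal between arrays within 0.01, so they are background-subtracted and quantile normalized, while the exact steps are not given in the sources used here. Each of its columns correlated best with its own array of the non-normalized table (Spearman 0.987 to 0.989). Slides, scan dates and batches are not given in the sources used here.

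The non-normalized signals were background-corrected with the normexp model on negative control values inferred from the detection p (neqc of limma 3.58.1 in R 4.3.3, offset 16), quantile normalized and put on the log2 scale. A probe was tested when its detection p was under 0.05 on at least 2 of the 6 arrays (20114 of 45281 probes). For each gene symbol the probe with the highest mean over the 6 arrays was taken, which left 14286 genes. Where a gene has several tested probes, opposite calls arose for 73 of 2841 genes with a called probe with JQ1 (2.57%), 3 of 792 with GDC-0449 (0.379%) and 62 of 2686 between the drugs (2.31%). Gene names are those of the deposited table. Of the tested symbols 8721 match a current symbol of the mouse RefSeq table used (GRCm38.p6, for names only), 2816 an older synonym and 2726 neither, and 23 that a spreadsheet had turned into dates are kept under their probe identifier (40 such probes in all). Current names are added for some of the older symbols printed, not for all.

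Groups were compared with limma's moderated test (lmFit, contrasts, eBayes; two-sided) in a single fit of all 6 arrays, which share the estimate of spread (3 residual and 5.12 prior degrees of freedom; median standard error 0.112). The comparisons were GDC-0449 with DMSO, JQ1 with DMSO, and JQ1 with GDC-0449, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The median standard deviation between the 2 arrays of a group was 0.0845 (DMSO), 0.0805 (JQ1) and 0.0802 (GDC-0449) on the log2 scale. A probe with a detection p of 0.05 or more on both arrays of a group has only a bound there. Its fold is given as "at least N-fold", the bright group's mean against the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own. Of the called genes, 781 with JQ1, 98 with GDC-0449 and 762 between the drugs had a compared group below background in this sense. These counts include any gene with both groups below background, for which no bound can be given.

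The 33 gene lists were fixed before the data were examined. They cover Hedgehog core readouts (too few tested for a set test), wider Hedgehog targets, pathway components, primary cilium, BET proteins with P-TEFb and 7SK genes, genes known to rise or to fall with BET inhibitors, histones, MYC and MYCN targets, G1 to S, G2 to M, CDK inhibitors and p53 targets, immediate-early genes, cholesterol synthesis, ATF4 targets, chaperones, NF-kB targets, interferon-stimulated genes, granule neuron progenitors, neuronal differentiation, neural stem cells, astrocytes, oligodendrocytes, microglia, endothelium, fibroblasts, WNT, NOTCH and TGF-beta targets, hypoxia and glycolysis, apoptosis, ribosomal proteins and reference genes. Lists with at least 4 tested genes (32) were tested with camera at a preset correlation of 0.01, adjusted over lists within a comparison. With an estimated correlation 2 calls held, those of the MYC target and G1 to S lists with GDC-0449. The fry test asks whether a list's genes move on balance in a single direction. The rule for named genes, also fixed before the data were examined, takes 16 pathway and BET genes always, the 8 largest rises and falls past the threshold per drug whose arrays do not overlap between the groups (5 each way between the drugs), and up to 4 members of each list described, those with the smallest adjusted p. Genes named outside that rule are said to be, and results of some genes within it are not reported here.

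The overlap and correlation of both comparisons with DMSO are given beside 50 simulations of unchanged groups that share the controls. The moderated test was tried before use on simulated log2 values. For a simulated comparison of JQ1 with DMSO on 14286 genes, it recovered 49.3% of 75 genes changed 1.5-fold, 97.3% of 75 changed 2-fold and 100% of 50 changed 4-fold. It called 173 genes, 13 of them unchanged, and 0 in a simulated drug without effect. Background correction, normalization, the detection filter and the choice of probe were not part of that simulation. Far fewer genes were changed in it than passed with JQ1. Alternatives fixed before the data were examined were another background correction (normexp with offset 50) or none (floor of 16), median centring or cyclic loess in place of quantile normalization, the authors' processed values, no filter or a stricter one (detection p under 0.01 on all 6 arrays), every probe on its own or the mean of a gene's probes, a variance trend with robust fitting, only the arrays compared, the replicate number as a block, a fold threshold of 1.5, and each array left out in turn. Median centring set the median over all 45281 probes equal between arrays. Most of these probes were not detected, so it need not even out brightness between arrays. No sample was left out of the comparisons.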

Results

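Gene expression was measured on Illumina BeadArrays in SmoWT-MB cells, a mouse medulloblastoma line deficient for Ptch, the receptor that restrains Hedgehog signalling. The cells had been treated for 6 h with the solvent DMSO, with JQ1, an inhibitor of the BET bromodomain proteins, or with GDC-0449 (vismodegib), an inhibitor of the Hedgehog signal transducer SMO. Each of the 3 groups had 2 arrays, and the doses are not given in the sources used here. The labels do not say whether the arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. Total signal was 18.5 M and 15.6 M intensity units on the DMSO arrays, 13.7 M and 14.2 M on the JQ1 arrays, and 13.8 M and 13.9 M on the GDC-0449 arrays. Between 18161 and 19038 of the 45281 probes were detected per array (40.1 to 42.0%), and 14286 genes were tested. Across genes, which are not independent replicates, arrays of the same group correlated at r = 0.996, DMSO with GDC-0449 arrays at 0.989 to 0.990, and DMSO with JQ1 arrays at 0.958 to 0.959. The number of arrays limits the precision. Fold changes below are on the log2 scale with the standard error of the fit (n = 2 arrays per group), and p-values are adjusted over all genes tested unless stated.

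The first question was how a SMO inhibitor changes expression in these cells. Hedgehog feedback genes that serve as readouts of the pathway were lower with GDC-0449. Hhip, a secreted antagonist of Hedgehog ligands (chromosome 8), fell by 1.94 ± 0.10 (adjusted p = 0.00012). Ptch1 fell by 1.83 ± 0.12 (adjusted p = 0.000273). Gli2, a transcription factor of the pathway, fell by 0.78 ± 0.10, Ccnd1 (cyclin D1) fell by 0.92 ± 0.10 and Ccnd2 (cyclin D2) fell by 0.88 ± 0.11. One of the 3 tested Ccnd2 probes did not follow (0.11, adjusted p = 0.524). Smo (−0.10, adjusted p = 0.628), Gli3 (−0.02, adjusted p = 0.893) and Sufu (−0.30, adjusted p = 0.238) did not pass the threshold, except Sufu with median centring (−0.50). Nor did Myc (0.30, adjusted p = 0.253), Hexim1 (0.15, adjusted p = 0.393) or the BET genes Brd2 (0.32) and Brd3 (−0.02). Brd2 did pass with normexp and offset 50 (0.31) and with a variance trend (0.32). No probe of Gli1 or Mycn was above background on any array, so their levels are not known from these data. Where the Ptch1 probe lies relative to the disrupted part of that gene is not known here either.

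**Figure D1:**
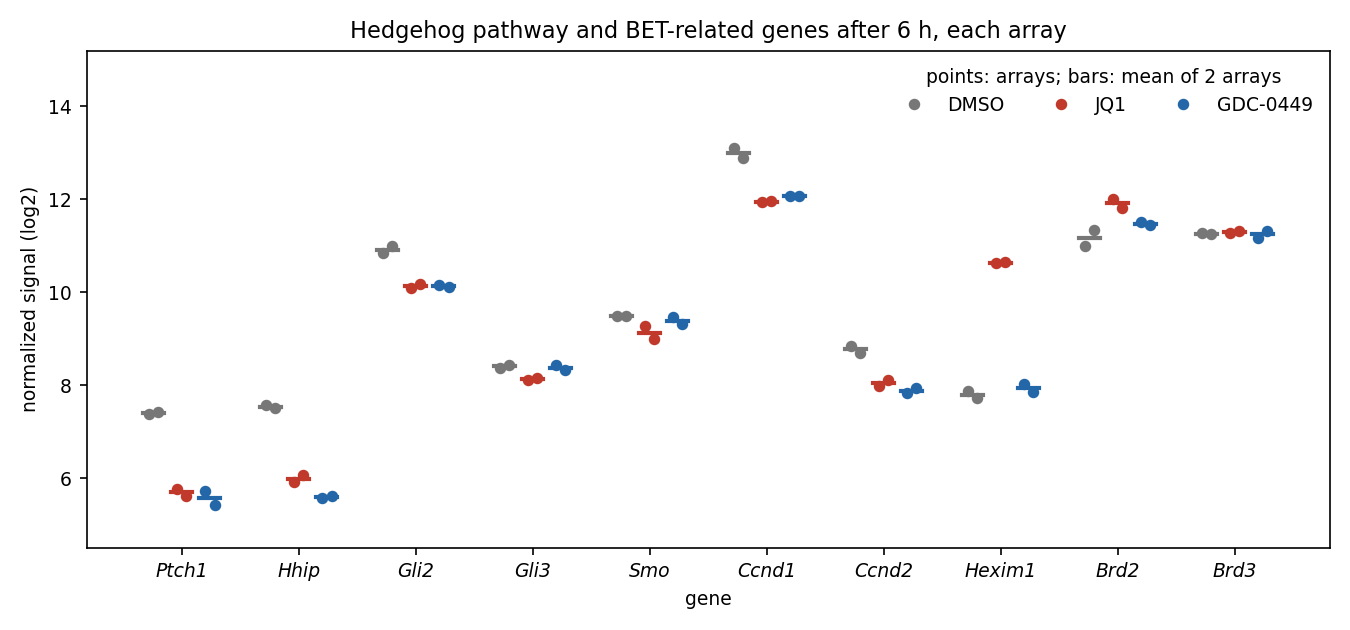
Normalized log2 signal of Hedgehog pathway and BET-related genes on each array (points, 2 per group) with the mean of the 2 arrays (bars). Ptch1 and Hhip are lower with both drugs, and Hexim1 is higher with JQ1 (2.83).

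Of the wider list of Hedgehog target genes, 11 of 19 tested members fell and 2 rose with GDC-0449 (11 and 5 adjusted over the list alone; median −0.49, camera adjusted p = 0.000404, adjusted p = 0.124 with an estimated correlation). The list holds Ptch1 and Hhip. Its other members that fell included Gpr153 (−1.81 ± 0.10) and Cdk6, a partner kinase of the D cyclins (−1.23 ± 0.10). Genes of the machinery of ribosome and nucleotide production that are known MYC and MYCN targets fell as a set, with 22 of 38 lower and none higher (29 lower adjusted over the list alone; median −0.42, camera adjusted p = 1.57e-14, adjusted p = 0.0478 with an estimated correlation). They included Srm, spermidine synthase (−0.99 ± 0.12), Bop1, a ribosome biogenesis factor (−0.79 ± 0.10), Pa2g4 (−0.72 ± 0.10) and Pprc1 (−0.66 ± 0.10). Genes of the G1 to S transition fell in 20 of 32 cases with none higher (25 lower adjusted over the list alone; median −0.52, camera adjusted p = 8.23e-14, adjusted p = 0.0478 with an estimated correlation). Among them were Ung, which removes uracil from DNA (−1.51 ± 0.10), the replication licensing factor Cdt1 (−0.83 ± 0.11), the chromatin assembly factor Chaf1b (−0.86 ± 0.11) and the origin recognition gene Orc1l, at least 1.85-fold lower because it was not above background with GDC-0449. The MYC target and G1 to S lists share no tested member.

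Genes of the ATF4 amino acid stress response also fell with GDC-0449, 20 of 28 lower and 1 higher (22 and 1 adjusted over the list alone; median −0.58, camera adjusted p = 1.57e-14, adjusted p = 0.124 with an estimated correlation). The glutathione-degrading enzyme Chac1 fell by 1.53 ± 0.10. The pseudokinase Trib3 fell by 1.35 ± 0.09, while Ddit4, an inhibitor of mTORC1, was the member that rose (1.06 ± 0.09). Slc7a11, the cystine transporter, fell by 1.67 ± 0.10 on the probe taken, but its other tested probe did not pass (−0.16, adjusted p = 0.495). That probe becomes the brighter of the 2 without DMSO replicate 1, where the gene's value is −0.29 and past no threshold. Markers of cerebellar granule neuron progenitors rose, 7 of 15 higher and 1 lower (11 and 1 adjusted over the list alone; median 0.31, camera adjusted p = 3.4e-05, adjusted p = 0.124 with an estimated correlation). With median centring the list passed again but its median was 0.01, so under that scaling its rise is one relative to other genes. The homeobox gene Barhl1 rose by 1.53 ± 0.09 and Sox4 rose by 0.99 ± 0.10. Neuronal differentiation genes rose in 8 of 22 cases with 1 lower (11 and 1 adjusted over the list alone; median 0.27, camera adjusted p = 0.000498, adjusted p = 0.124 with an estimated correlation), and the median was 0.12 with median centring. They included the adhesion molecule Cntn2 (0.81 ± 0.09) and the RNA-binding protein Elavl3 (0.77 ± 0.09).

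CDK inhibitors and p53 targets passed the list test as higher with GDC-0449, with 7 of 21 members higher and 2 lower, also adjusted over the list alone (median 0.16, camera adjusted p = 0.00996, adjusted p = 0.181 with an estimated correlation). With median centring the median was −0.02. Trp53inp1 rose by 1.30 ± 0.11 and Bbc3, which encodes the cell death protein PUMA, by 0.73 ± 0.10. Of 9 genes known to rise with BET inhibitors, 3 rose with GDC-0449 (4 adjusted over the list alone; median 0.25, camera adjusted p = 0.00237, adjusted p = 0.167 with an estimated correlation). With median centring the median of this list was 0.02. Single members of this list are not named for GDC-0449, since each of the 3 calls was lost without 1 or more arrays. The G2 to M list passed as higher with a median of 0.14 and 1 of 26 members higher (0 adjusted over the list alone; camera adjusted p = 0.0356, adjusted p = 0.424 with an estimated correlation). That call was lost without DMSO replicate 2 (median 0.13), without JQ1 replicate 1 (0.12) and without GDC-0449 replicate 2 (0.11), and with median centring its median was −0.14. The remaining lists did not pass with GDC-0449 (camera adjusted p = 0.0694 to 0.811). Some passed under an alternative, the histone list as higher under 3, and the BET and P-TEFb list (higher), the TGF-beta and BMP list (higher) and the list known to fall with BET inhibitors (lower) under 1 each. In them the sign of the median differed from that of the mean or a set test for interferon-stimulated genes, neural stem cell genes, Hedgehog pathway components and ribosomal protein genes. Examples of single members of these that changed were Stk36, a kinase of the pathway component list (1.34 ± 0.11), Fosl2 (−1.48 ± 0.10) and Egr2 (−1.16 ± 0.13) of the immediate-early list, and the endothelial marker Sox18 (−1.96 ± 0.10).

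In all, 1788 genes (12.5% of those tested) passed the threshold with GDC-0449, 829 higher and 959 lower. Of these, 35 and 77 changed by at least 2-fold. The 8 largest rises were those of Hebp1 (1.78 ± 0.13), 6330404C01Rik (now Cemip, 1.63 ± 0.11), C530044C16Rik, Barhl1, Bat2 (now Prrc2a), Stk36, Pik3r3 and Mfap4, the last at 1.32 ± 0.10. The 8 largest falls were those of 1700021K02Rik (now Tbata, −2.90 ± 0.10), the glutamate transporter Slc1a1 (−2.26 ± 0.11), Synpo (−2.20 ± 0.11), Sox18, Hhip, Kank1, D630003M21Rik and Ptch1. The count depended on single arrays and was 416 without DMSO replicate 1, 591 without DMSO replicate 2, 541 without GDC-0449 replicate 1 and 606 without GDC-0449 replicate 2. With median centring in place of quantile normalization it was 3311, of which 10.4% were higher against 46.4%, around a median over all genes of −0.18, while 44.9% were higher with cyclic loess. Of the calls, 1285 of the 1788 kept their call and direction.

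The second question was how a BET inhibitor changes expression in the same cells, and whether Hedgehog target genes are among those that change. With JQ1, Ptch1 fell by 1.70 ± 0.12 (adjusted p = 2.05e-05), Hhip by 1.55 ± 0.10 (adjusted p = 1.11e-05), Ccnd1 by 1.05 ± 0.10 (adjusted p = 9.67e-05), Gli2 by 0.79 ± 0.10 (adjusted p = 0.000349) and Ccnd2 by 0.72 ± 0.11 (adjusted p = 0.000705). Smo (−0.36, adjusted p = 0.0367) and Gli3 (−0.26, adjusted p = 0.0459) were lower with calls that single arrays ended. That of Smo was lost without DMSO replicate 1 (−0.37), DMSO replicate 2 (−0.35) or JQ1 replicate 2 (−0.22), with the authors' processed values (−0.36) and with no filter on dim probes (−0.36). Both other tested Smo probes were lower too (−0.40, adjusted p = 0.0406, and −0.48, adjusted p = 0.00649, over all probes). The call of Gli3 was lost without any 1 of the 6 arrays, at −0.23 to −0.29. It was also lost with every probe tested on its own, with only the arrays compared and with the replicate number as a block (−0.26 in each). Sufu did not pass (0.20, adjusted p = 0.323), though another of its probes did (0.94, adjusted p = 0.000638).

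Of the wider list of Hedgehog target genes, 11 of 19 fell and 2 rose with JQ1, both over all genes and adjusted over the list alone (median −0.39, camera adjusted p = 0.00462, adjusted p = 0.172 with an estimated correlation). Cdk6 fell by 1.46 ± 0.10. The lists of genes known to respond to BET inhibitors in other cells were tested next. Each of the 9 tested genes known to rise did so, also adjusted over the list alone (median 2.52, camera adjusted p = 5.86e-08, adjusted p = 0.102 with an estimated correlation). Hexim1, a component of the 7SK complex that holds the elongation factor P-TEFb inactive (chromosome 11), rose by 2.83 ± 0.11 (adjusted p = 2.01e-06). The linker histone gene Hist1h1c (now H1f2, chromosome 13) rose by 2.89 ± 0.09 (adjusted p = 1.44e-06). Of 7 genes known to fall, 5 fell and none rose, also adjusted over the list alone (median −0.58, camera adjusted p = 0.0231, adjusted p = 0.354 with an estimated correlation). The list's call was lost with the mean of the probes of a gene. Members that fell included Cdk6, the transcription factor E2f2 (−1.02 ± 0.10) and Id2 (−0.58 ± 0.09), and 3 of the 7 also stand in the Hedgehog list.

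The largest group that rose with JQ1 was that of the histone genes, with 42 of 60 higher and 5 lower (43 and 7 adjusted over the list alone; median 1.19, camera adjusted p = 7.1e-11, adjusted p = 0.0973 with an estimated correlation). It holds 7 of the 9 genes known to rise with BET inhibitors. Hist1h2bm rose by 2.71 ± 0.09 and Hist2h2aa1 by 2.91 ± 0.10. Many histone genes of a family are nearly identical, so values of single members are uncertain. Of the BET proteins and the P-TEFb and 7SK genes, 9 of 18 rose and 1 fell, also adjusted over the list alone (median 0.28, camera adjusted p = 0.0367, adjusted p = 0.236 with an estimated correlation). Brd2 rose by 0.75 ± 0.13 (adjusted p = 0.00208) and Hexim2 fell by 1.20 ± 0.10. Brd3 did not pass (0.04, adjusted p = 0.766). The call of this list was lost without JQ1 replicate 1 (median 0.28), with median centring (0.02), a stricter filter on dim probes (0.25), every probe tested on its own (0.23) and the mean of the probes of a gene (0.24).

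Immediate-early and serum-response genes rose with JQ1 in 16 of 24 cases with 1 lower (18 and 1 adjusted over the list alone; median 0.60, camera adjusted p = 0.000261, adjusted p = 0.172 with an estimated correlation). Fos rose by 2.77 ± 0.14, Egr1 by 2.04 ± 0.09 and Junb by 1.08 ± 0.11. Atf3, not above background with DMSO, was at least 2.29-fold higher. CDK inhibitors and p53 targets rose in 13 of 21 cases with 2 lower, also adjusted over the list alone (median 0.43, camera adjusted p = 0.00476, adjusted p = 0.172 with an estimated correlation). They included the growth arrest genes Gadd45b (2.19 ± 0.10) and Gadd45a (1.71 ± 0.13) and Trp53inp1 (1.60 ± 0.11). Heat shock and endoplasmic reticulum chaperones rose in 12 of 22 cases with 3 lower (15 and 3 adjusted over the list alone; median 0.42, camera adjusted p = 0.00757, adjusted p = 0.172 with an estimated correlation). Those with the smallest p, Pdia4 (1.10 ± 0.10), Creld2 (1.09 ± 0.10), Calr (1.12 ± 0.11) and Sdf2l1 (0.99 ± 0.10), act in the endoplasmic reticulum.

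Of the MYC and MYCN targets, 28 of 38 fell and 1 rose with JQ1 (28 and 3 adjusted over the list alone; median −0.47, camera adjusted p = 4.1e-06, adjusted p = 0.102 with an estimated correlation). Among them were the folate transporter Slc19a1 (−1.53 ± 0.11), Srm (−1.37 ± 0.12) and Pprc1 (−1.20 ± 0.10). Myc itself lay near background and did not pass (0.33, adjusted p = 0.125), though it did as higher without GDC-0449 replicate 1 (0.32) or 2 (0.32) and with only the arrays compared (0.33). Of the G1 to S genes, 23 of 32 fell and none rose, also adjusted over the list alone (median −0.43, camera adjusted p = 4.56e-05, adjusted p = 0.114 with an estimated correlation). They included the replicative helicase genes Mcm3 (−1.51 ± 0.15) and Mcm2 (−1.12 ± 0.10) and Ung (−1.43 ± 0.10). Of the ATF4 genes, 21 of 28 fell and 3 rose (23 and 3 adjusted over the list alone; median −0.70, camera adjusted p = 2.67e-05, adjusted p = 0.228 with an estimated correlation). Nupr1 fell by 2.44 ± 0.10 and the methionyl-tRNA synthetase Mars by 1.39 ± 0.09, and Ddit4 rose by 1.33 ± 0.09. Slc7a11, not above background with JQ1, was at least 3.34-fold lower on the probe taken, while its other tested probe did not pass (−0.36, adjusted p = 0.0611).

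The remaining lists did not pass as sets with JQ1 (camera adjusted p = 0.0525 to 0.839), although many hold single genes that changed. With JQ1 51.3% of all tested genes passed, 3620 higher and 3703 lower, so counts near that share do not set a list apart. Counts adjusted over the list alone equalled those over all genes except where given. Of neuronal differentiation genes 5 of 22 rose and 11 fell (13 adjusted over the list alone), with the migration gene Dcx at −1.60 ± 0.12 and the neurofilament partner Ina at 1.43 ± 0.11. Of granule neuron progenitor markers 5 of 15 rose and 6 fell, with Sox11 at 1.08 ± 0.09 and Barhl1 at −0.77 ± 0.09. Of neural stem cell and radial glia genes 5 of 15 rose and 7 fell, with Msi1h (now Msi1) at −1.74 ± 0.12. Of oligodendrocyte lineage markers 2 of 8 rose and 4 fell (5 adjusted over the list alone), with Mbp at −2.16 ± 0.11 and Pdgfra, not above background with JQ1, at least 3.83-fold lower. Of astrocyte markers 1 of 8 rose and 4 fell, with the sodium pump subunit Atp1b2 at 1.56 ± 0.11 and the connexin Gja1 at −1.42 ± 0.14. Among markers of cells that a culture could hold beside the tumour cells, 2 of 5 microglia and macrophage markers rose and none fell, 1 of 6 endothelial markers rose and 2 fell, and 2 of 7 fibroblast markers rose and 2 fell. Examples are Cd68 (1.18 ± 0.11), Ramp2 (−1.69 ± 0.11) and Thy1 (−1.53 ± 0.11).

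Of the Hedgehog pathway components 3 of 18 rose and 10 fell with JQ1 (11 lower adjusted over the list alone), with the co-receptor Cdon at 1.35 ± 0.13 and the ciliary protein Evc2 at −1.21 ± 0.10. Of the primary cilium genes 7 of 25 rose and 8 fell, with Ift52 at −1.18 ± 0.10. Of the G2 to M genes 1 of 26 rose and 10 fell (9 adjusted over the list alone; camera adjusted p = 0.0525), and the list passed as lower under 8 of the alternatives. Examples are Bub1b at −0.90 ± 0.10 and Top2a at −0.66 ± 0.10. Of NOTCH targets and ligands 5 of 11 rose and 4 fell, with Mfng at −2.70 ± 0.11. Of WNT targets 3 of 6 rose and 3 fell, with the WNT inhibitor Wif1 at −1.57 ± 0.10. Of TGF-beta and BMP targets 2 of 7 rose and 2 fell (3 higher adjusted over the list alone), with Msx1 at 1.21 ± 0.13. Of interferon-stimulated genes 4 of 12 rose and 5 fell (6 lower adjusted over the list alone), with Stat2 at 1.40 ± 0.12 and Rsad2, above background on 1 JQ1 array, at −1.77 ± 0.11. Of NF-kB targets 4 of 7 rose and 1, Nfkb1, fell (−1.22 ± 0.12). Of cholesterol biosynthesis genes 9 of 28 rose and 3 fell. Of hypoxia and glycolysis genes 9 of 23 rose and 2 fell (8 higher adjusted over the list alone; the list passed as higher with a stricter filter on dim probes), with P4ha1 at 1.14 ± 0.12 and the phosphofructokinases Pfkp (1.03 ± 0.12) and Pfkl (0.97 ± 0.11). Of apoptosis regulators 7 of 20 rose and 5 fell (6 lower adjusted over the list alone), with Bcl2l11, which encodes BIM, at 1.46 ± 0.10. Of ribosomal protein genes 1 of 57 rose and 3 fell (1 lower adjusted over the list alone), with Rpl22 at −0.67 ± 0.10. That is a far smaller share than the 51.3% of all tested genes. Of commonly used reference genes 5 of 12 rose and 2 fell, with Gusb at −1.45 ± 0.13, Polr2a at 1.15 ± 0.15 and B2m at 1.06 ± 0.10. The sign of the median differed from that of the mean or a set test for the endothelial, WNT, neural stem cell and NOTCH lists.

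In all, 7323 genes passed the threshold with JQ1 (51.3% of those tested), 3620 higher and 3703 lower, of which 642 and 833 changed by at least 2-fold. The largest rises were those of 5031425E22Rik (4.04 ± 0.09, adjusted p = 1.02e-06), Mylk, myosin light chain kinase (3.63 ± 0.15), the long non-coding RNA Dleu2 (3.38 ± 0.11), Gch1, which makes the first intermediate of tetrahydrobiopterin (2.98 ± 0.11), Ccno (2.92 ± 0.15), Hist2h2aa1, Hist1h1c and Hexim1. The largest falls were those of Islr2 (−3.73 ± 0.11, adjusted p = 1.13e-06), Sdpr (now Cavin2, −3.39 ± 0.14), Cog7 (−3.34 ± 0.09), 1700021K02Rik (now Tbata, −3.25 ± 0.10), the tight junction protein Cldn2 (−3.22 ± 0.16), the TIE2 ligand Angpt1 (−3.20 ± 0.09), Zfp239 (−3.17 ± 0.10) and Samd9l (−3.09 ± 0.11). The near-even split did not hold with median centring. With cyclic loess 47.4% of the calls were higher, against 49.4%, but that method, like quantile normalization, balances changes around 0 by construction. With median centring 7440 genes passed, of which 21.2% were higher, around a median over all genes of −0.24. Of the 7323 calls, 5269 kept their call and direction with none reversed.

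**Figure D2:**
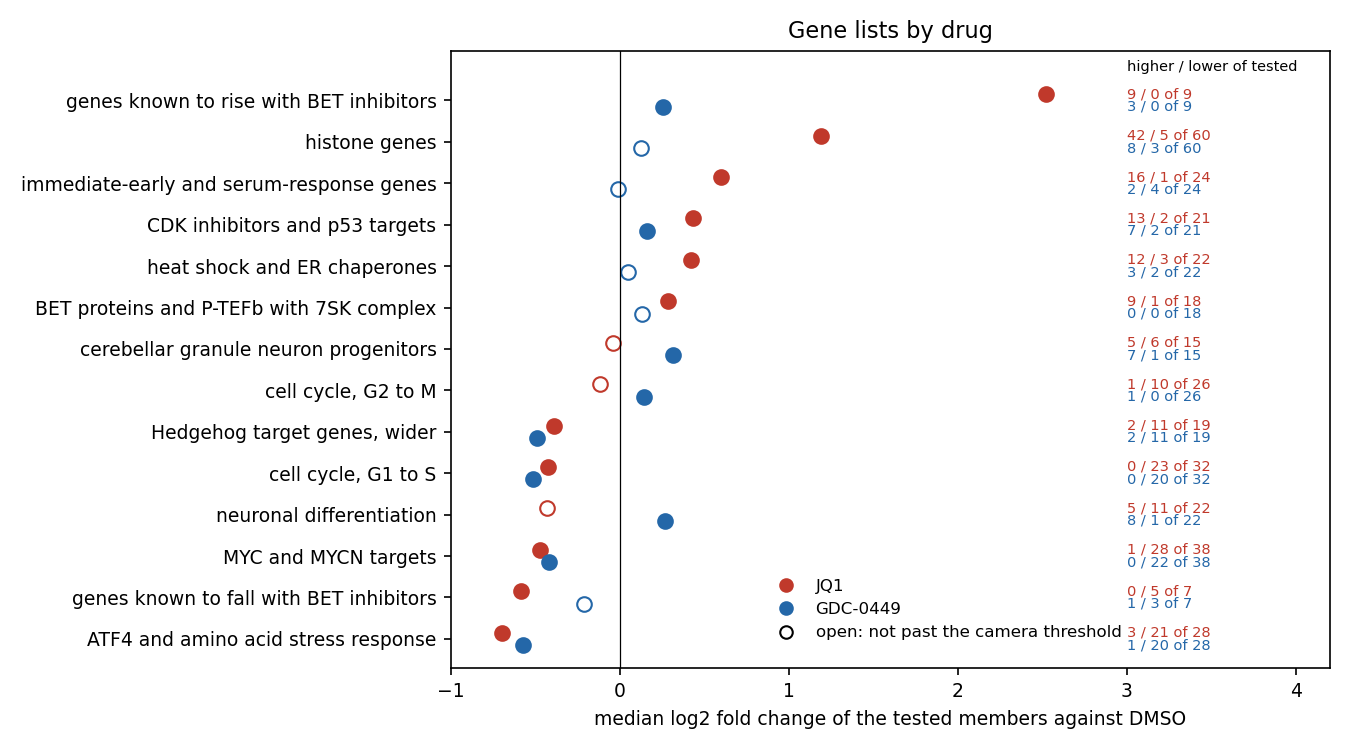
Median log2 fold change against DMSO of the tested members of each of the 14 lists past the camera threshold with either drug (filled points; open points did not pass), with the number of members higher and lower at right. MYC target, G1 to S, ATF4 and Hedgehog target lists lie below 0 with both drugs and the histone list lies at 1.19 with JQ1; with median centring the GDC-0449 medians of the G2 to M list (−0.14) and of the CDK inhibitor and p53 list (−0.02) fall below 0.

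Quantile normalization was set against median centring for each list. With median centring the all-gene median was −0.24 with JQ1, −0.18 with GDC-0449 and −0.06 between the drugs. Relative to these shifts, each called list kept its direction, 11 of 11 with JQ1, 9 of 9 with GDC-0449 and 6 of 6 between the drugs. Of these, 10, 8 and 6 passed again. Both outcomes were largely built in and are weak checks. Taking off the all-gene median removes the shift that the scaling adds, and camera compares a list with other genes. The lists that did not pass again were the BET and P-TEFb list with JQ1 and the G2 to M list with GDC-0449. Genes with a group below background were then set to their bound, or to no change where no bound could be given. No called list's median changed sign, and the largest change was 0.17.

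The direct test between the drugs asked where a BET inhibitor and a SMO inhibitor differ. In it 47.2% of all tested genes passed, so counts near that share do not set a list apart. Hhip was 0.39 ± 0.10 higher with JQ1 than with GDC-0449 (adjusted p = 0.0116), a call that was lost without JQ1 replicate 2 (0.32), without GDC-0449 replicate 1 (0.37) and with median centring (0.18). The difference did not pass for Ptch1 (0.13 ± 0.12, adjusted p = 0.429), Gli2 (0.00 ± 0.10, adjusted p = 0.975), Ccnd1 (−0.13 ± 0.10, adjusted p = 0.347) or Ccnd2 (0.16 ± 0.11, adjusted p = 0.247). Nor did it for Gli3 (−0.24, adjusted p = 0.068) or Smo (−0.26, adjusted p = 0.113), though 6 and 4 of the alternatives called them lower with JQ1. Both other tested Smo probes passed as lower (−0.49, adjusted p = 0.0205, and −0.53, adjusted p = 0.00455, over all probes). The other tested Ccnd2 probes passed in opposite directions (−0.41, adjusted p = 0.0134, and 0.31, adjusted p = 0.049, over all probes). Of the wider list of Hedgehog targets 6 of 19 were higher with JQ1 and 5 lower, also adjusted over the list alone. The list did not pass (camera adjusted p = 0.869). Gpr153 was 1.42 ± 0.10 higher with JQ1, and the NOTCH and Hedgehog target Hey1 (−1.09 ± 0.10) and the steroid dehydrogenase Hsd11b2 (−1.24 ± 0.11) were lower.

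Histone genes were higher with JQ1 than with GDC-0449 in 43 of 60 cases with 1 lower, also adjusted over the list alone (median 1.06, camera adjusted p = 1.78e-13, adjusted p = 0.071 with an estimated correlation). So were all 9 genes known to rise with BET inhibitors (median 2.02, camera adjusted p = 8.98e-08, adjusted p = 0.144 with an estimated correlation; 9 also adjusted over the list alone), with Hexim1 at 2.69 ± 0.11. Immediate-early genes were higher in 16 of 24 cases with 1 lower (18 and 1 adjusted over the list alone; median 0.51, camera adjusted p = 2.74e-05, adjusted p = 0.223 with an estimated correlation). Fos was at 2.61 ± 0.14, Egr1 at 2.24 ± 0.09 and Fosl2 at 1.75 ± 0.10. Heat shock and endoplasmic reticulum chaperones were higher in 14 of 22 cases with 2 lower (16 and 3 adjusted over the list alone; median 0.54, camera adjusted p = 0.00444, adjusted p = 0.223 with an estimated correlation), with Herpud1 at 0.88 ± 0.09. The call was lost with a stricter filter on dim probes. Neuronal differentiation genes were lower with JQ1 than with GDC-0449 in 13 of 22 cases and higher in 3 (15 and 3 adjusted over the list alone; median −0.49, camera adjusted p = 0.00329, adjusted p = 0.223 with an estimated correlation). Neurod2, a neuronal transcription factor (−2.26 ± 0.12), Dcx (−2.19 ± 0.12) and Cntn2 (−1.94 ± 0.09) were among them. The G2 to M genes were lower with JQ1 in 16 of 26 cases with none higher, also adjusted over the list alone (median −0.35, camera adjusted p = 0.00167, adjusted p = 0.314 with an estimated correlation). Bub1b was at −0.93 ± 0.10, Top2a at −0.86 ± 0.10, Cenpa at −0.69 ± 0.10 and Mki67 at −0.54 ± 0.09. The remaining lists did not pass (camera adjusted p = 0.0535 to 0.97). Their median, mean or set tests differed in sign for the CDK inhibitor and p53, ATF4, G1 to S, ribosomal protein and NF-kB lists, and with median centring the ribosomal protein list passed as higher (median 0.15, against −0.01). The hypoxia and glycolysis list (median 0.28, camera adjusted p = 0.0535) passed as higher with JQ1 under 7 of the alternatives. The cilium list and the BET and P-TEFb list passed with no filter on dim probes, and the astrocyte list with every probe tested on its own.

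Between the drugs 6745 genes differed, 3334 higher and 3411 lower with JQ1. The 5 largest higher values with JQ1 were those of Mylk (3.54 ± 0.15), 5031425E22Rik (3.50 ± 0.09), Gch1 (3.22 ± 0.11), Espn (2.83 ± 0.11; above background on 1 of the GDC-0449 arrays) and Hist2h2aa1 (2.71 ± 0.10). The 5 largest lower values were those of Igfbp5 (−3.96 ± 0.13), Angpt1 (−3.74 ± 0.09), Emp1 (−3.64 ± 0.12), Sdpr (−3.64 ± 0.14) and Islr2 (−3.63 ± 0.11). Of the BET genes, Brd2 was 0.43 ± 0.13 higher with JQ1 (adjusted p = 0.029), a call lost without JQ1 replicate 1 (0.33), GDC-0449 replicate 1 (0.46) or GDC-0449 replicate 2 (0.41) and with no filter on dim probes (0.43). Of the 3 other tested Brd2 probes, 2 passed as higher (0.80, adjusted p = 0.000347, and 0.57, adjusted p = 0.00356, over all probes) and 1 did not (0.19, adjusted p = 0.234). Sufu was 0.50 ± 0.15 higher (adjusted p = 0.0292), a call lost without JQ1 replicate 2 (0.33) or GDC-0449 replicate 1 (0.33), with median centring (0.33), with no filter on dim probes (0.50) and on the authors' processed values (0.56). Its other tested probe was 1.12 higher (adjusted p = 0.000276, over all probes). With median centring 37.8% of the 6109 genes that differed were higher with JQ1, against 49.4%, and with cyclic loess 47.1% were.

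The comparisons with DMSO shared called genes. Both drugs raised 395 genes and lowered 618, where independent lists of these lengths would share 210.1 and 248.6 (n1 × n2 / N). With median centring, which need not even out brightness between arrays, these counts were 98 and 2064, and with cyclic loess 415 and 707. Simulated unchanged groups against the same controls shared 0, which carries little information because such groups give almost no calls. A further 95 genes were higher with JQ1 and lower with GDC-0449 (243 for independent lists), and 193 the reverse (214.9). The genes that both drugs lowered made up 64.4% of those lowered by GDC-0449, and those that both raised made up 47.6% of those it raised. Among the shared genes, 177 of the 395 and 282 of the 618 differed in size between the drugs. Across all genes tested, which are not independent replicates, the fold changes of both drugs correlated at Pearson r = 0.326 and Spearman rho = 0.33, against higher values of 0.501 and 0.479 for simulated unchanged groups that share the controls. The sign was the same for 62.4% of genes, against 66.7% simulated. The covariance was 0.0609 against 0.00774 simulated, a difference of 0.0532 (50 simulations). With single arrays, each drug set against a different DMSO array so that no control was shared, r was 0.226 to 0.267 over 8 combinations. The difference of 0.0532 already leaves out what shared controls add at the spread between these arrays. The 2 DMSO arrays cannot be split into parts of 2, so a larger part from the shared controls stays open. The overlap counts moved with single arrays, to 77 and 167 without DMSO replicate 1, 135 and 220 without DMSO replicate 2, 114 and 217 without GDC-0449 replicate 1, and 119 and 255 without GDC-0449 replicate 2.

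**Figure D3:**
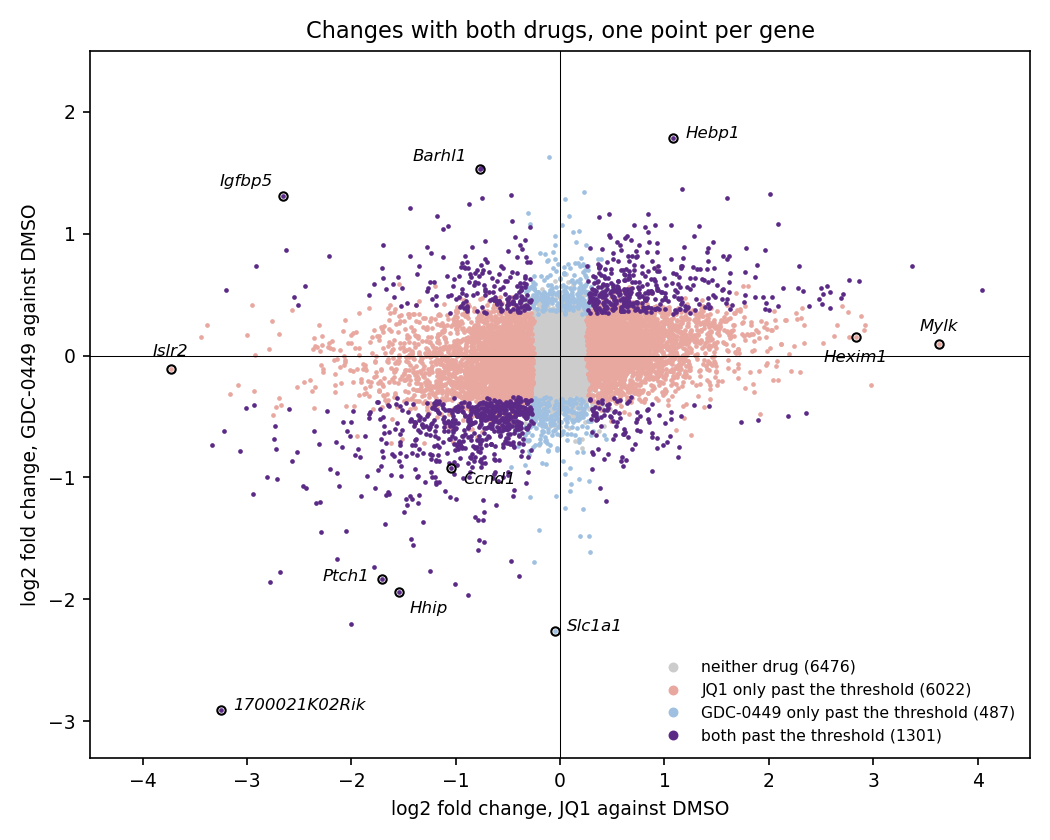
Log2 fold change of each gene with JQ1 (horizontal) and with GDC-0449 (vertical), both against the same DMSO arrays; colours mark genes past the threshold with both drugs (1301), JQ1 alone (6022), GDC-0449 alone (487) or neither (6476), and circles mark genes named in the text. Ptch1, Hhip, Ccnd1 and 1700021K02Rik lie at lower left, Slc1a1 near 0 for JQ1, and Igfbp5 and Barhl1 at upper left.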

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

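The alternatives below were fixed before the data were examined. A left-out array leaves a group with 1 array, which is then assumed to vary like the others, and the cause of each change was not tested unless the alternative's construction shows it. Of the genes named by rule, 117 of 135 calls with JQ1, 45 of 87 with GDC-0449 and 122 of 128 between the drugs kept their call and direction under all alternatives that tested them, and none reversed. Leaving out an array ended 11, 38 and 5 of them, and median centring 12, 18 and 2. Apart from 3 list results that changed sign, 25 gained a call and 10 lost it. Median centring lowers list medians with the all-gene median, so more medians near 0 changed sign without a call in either fit. The 3 with a call in 1 or both fits were those of the G2 to M list (−0.143, call lost) and the CDK inhibitor and p53 list (−0.024, call kept) with GDC-0449, and of the ribosomal protein list between the drugs (0.148, call gained). Signal over background limits dim genes, and levels of genes whose probes are below background on all arrays are not known.

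The count with GDC-0449 (1788; 829 higher, 959 lower) was 2844 (1364 and 1480) with normexp and offset 50, 2864 (1374 and 1490) with a variance trend and robust fitting, 3311 (345 and 2966) with median centring and 667 (272 and 395) with a fold threshold of 1.5, which keeps fewer genes by construction. Without background correction 1248 genes were higher. Over the left-out arrays it ran from 416 to 1743, with 178 to 780 higher and 238 to 963 lower. The JQ1 count (7323) was within 1.5 times under the other alternatives, 5870 to 7173 over the left-out arrays, and 3882 (1830 and 2052) with the fold threshold. Its split moved to 1578 higher and 5862 lower with median centring. The count between the drugs (6745) was 5356 to 6631 over the left-out arrays and 3584 (1690 and 1894) with the fold threshold.

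The genes raised by both drugs (395) numbered 660 with normexp and offset 50, 594 without background correction, 98 with median centring, 630 with a stricter filter and 689 with a variance trend, and 77 to 312 over the left-out arrays. Those lowered by both (618) numbered 934 with normexp and offset 50, 927 with a variance trend, 2064 with median centring and 167 to 574 over the left-out arrays. The correlation of the fold changes (0.326) was 0.375 with median centring, 0.363 with cyclic loess and 0.304 to 0.357 over the left-out arrays. Lists past the threshold (11, 9 and 6 for JQ1, GDC-0449 and between the drugs) numbered 0, 2 and 0 with an estimated correlation, 24, 15 and 21 with fry, which does not compare a list with other genes, and 10 between the drugs without a filter on dim probes.

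Replicate numbers are shared between groups, but arrays of the same number did not deviate together (correlations 0.021, −0.009 and 0.054), so the numbers were not taken to pair the arrays. With the replicate number as a block the counts were 7265, 1567 and 6692.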

Other observations

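The tests of total signal, of the MYC transcript, of S phase and of cross-hybridisation below were chosen after the results were seen, as were the gene families by symbol prefix and the genes named in this part outside the rule.

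The histone genes did not move as a block with JQ1. All 11 tested H2B genes rose (median 2.56), as did 11 of 12 H4 genes (median 1.45), 10 of 11 H3 genes (median 1.14) and 3 of 4 H1 genes (median 1.57). Of 22 H2A genes 7 rose and 5 fell (median −0.15). The family counts include 10 genes outside the histone gene clusters, of which 5 rose and 1 fell (median 0.38). Within the histone gene clusters 6 H2A genes had higher values, between 0.65 and 2.92, and 10 had lower values within a narrow range, −0.41 to −0.17, with Hist2h2aa1 at 2.91 and Hist1h2ah at −0.41. In a scan of 55 symbol-prefix families of at least 15 genes, nucleoporin genes fell with JQ1 (10 of 16 lower, none higher, median −0.44, camera adjusted p = 0.0219, adjusted p = 0.896 with an estimated correlation), led by Nup210 (−1.41 ± 0.09). Genes of the large mitochondrial ribosome subunit also fell with JQ1 (20 of 42 lower, 2 higher, median −0.29, the same p in both tests), led by Mrpl36 (−1.40 ± 0.10). With GDC-0449 mitochondrial ribosome genes (Mrpl 2 of 42 lower, median −0.14, adjusted p = 0.0397; Mrps 2 of 27 lower, median −0.19, adjusted p = 0.036), RNA polymerase subunit genes (4 of 22 lower, median −0.18, adjusted p = 0.036) and genes with the prefix Rad (2 of 15 lower, median −0.18, adjusted p = 0.036) passed as lower. Few of their members passed on their own, and none of the families passed with an estimated correlation (adjusted p = 0.69).

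Among the 288 genes called in opposite directions by the drugs were Igfbp5, Barhl1, Cntn2 and Mycl1. Each of the 288 also passed the direct test, but this adds no support. For opposite changes the direct difference is larger than either change at the same standard error, so the outcome was fixed. Igfbp5, which binds insulin-like growth factors, fell by 2.65 ± 0.13 with JQ1 and rose by 1.31 ± 0.13 with GDC-0449. Barhl1 fell by 0.77 ± 0.09 and rose by 1.53 ± 0.09, and Cntn2 fell by 1.13 ± 0.09 and rose by 0.81 ± 0.09. Mycl1 (now Mycl) was the MYC family gene with a clear signal. It rose by 0.90 ± 0.09 with GDC-0449 and was 1.29 ± 0.09 lower with JQ1 than with GDC-0449, while its fall with JQ1 (−0.38 ± 0.09) did not pass without JQ1 replicate 2 (−0.34).

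With JQ1 51.3% of the tested genes passed, split nearly evenly between higher and lower. The dimmest genes did not make up the calls. Of the dimmest tercile 41.1% passed, against 60.9% of the middle and 51.8% of the brightest. Lower total signal alone does not account for the number of calls. The GDC-0449 arrays had the same mean total as the JQ1 arrays (13.9 M against 17.0 M intensity units for DMSO) and gave 24.4% as many calls. The 75th percentile of signal differed, at 107.1 and 112.2 on the JQ1 arrays and 124.3 and 128.5 on the GDC-0449 arrays. With DMSO it was 156.5 and 133.5, so a part of dimmer signal in the JQ1 calls stays open. The even split may come from quantile normalization, because the share of higher genes moved by 28.2 percentage points with median centring. That option aligns the median of all probes, of which 40.1 to 42.0% were detected per array, so it need not even out brightness. The DMSO arrays had the higher total signal, and its part in the shift was not tested. Cyclic loess balances changes around 0 by construction, so its shift of 2 points does not bear on this, and without spike-ins a broad change of RNA level stays open.

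MYC target, G1 to S and ATF4 genes fell with both drugs. A single odd DMSO array does not account for it, since against each DMSO array alone the highest of the 12 list medians was −0.373. Nor does the signal level of the genes, since the medians lay at or below percentile 0.01 of 10000 random lists matched on mean signal. Both drugs were set against the same DMSO arrays, so a shift common to these arrays stays open. Between the drugs none of the 3 lists passed (camera adjusted p = 0.445 to 0.97). The medians were −0.09 for MYC targets, 0.08 for G1 to S and −0.07 for ATF4 genes. That test cannot decide it, since DMSO cancels there. Whether the MYC or MYCN transcript fell cannot be told apart from no change, because 0 probes of Myc, Mycn and Mycl1 fell with both drugs while Mycn was below background and Myc near it, with 3 alternatives calling Myc higher with JQ1. What links the 3 lists stays open.

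Histone genes rose with JQ1. More cells in S phase might raise the G1 to S genes, whose median was −0.426. Their fall cannot decide this, since a drug could lower these transcripts whatever the share of cells in S phase. A single induced transcript that cross-hybridises would reach a single family, while genes of 5 of 5 histone families rose. Cross-hybridisation within a family stays open, since probe sequences were not used here. Why histone genes rose stays open.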
